A study of Rattus norvegicus with 2 samples.

How the data were processed

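Gene expression was measured in whole kidneys of female PCK rats, a strain with a mutation in Pkhd1 that serves as a model of autosomal recessive polycystic kidney disease. One group received pioglitazone, an agonist of the nuclear receptor PPAR-gamma, at 10 mg/kg by daily gavage from 4 to 20 weeks of age, and the other received vehicle with 0.5% DMSO. Kidney RNA was pooled within each group, and each pool was labelled with Cy3 and hybridised to 1 array. The labels contradict themselves on the pool: the design text speaks of 5 females per group and the labelling text of 3 rats. The normal +/+ rats that the treatment text mentions are not analysed here. The array product number in the design text and the array design in the file headers were not reconciled, and the spots were taken from the files.

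The deposited scanner files hold spot intensity on a linear scale. Per the file headers and the submitters' processing notes, Agilent Feature Extraction 10.7.3.1 subtracted background and removed spatial trends within each array, with no scaling between arrays. The deposited value table equals these processed intensity values at all 45018 features of each array, so it carries no log scale or centring of its own. Its column medians were 46.8 for vehicle and 47.7 for pioglitazone.

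Each array held 43379 spots besides its 1639 control spots. In the vehicle array 31127 spots (71.8%) were well above background, and in the pioglitazone array 31728 (73.1%). No spot was saturated. Of 153 negative control spots, 0 and 1 were well above background. Spots with an outlier flag on either array, 149 in all, were left out. Signals were put on a log2 scale and each array's 75th percentile was subtracted, which removed a shift of 0.08 between the arrays. Replicate spots of a probe were averaged. Probes were named through RefSeq accessions in a gene table of the GRCr8 assembly, without versions. This named 16959 of 40998 probes (41.4%), left 24039 unnamed, and gave no probe several symbols. The files' own annotation uses the rn4 build, so no coordinates are given. A gene took the value of its brightest probe and counted as measured when that probe was well above background and unsaturated on both arrays. Of 13435 named genes, 10484 were measured. Among 2418 genes with several measured probes, all probes had the same direction in 1560.

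With 1 array per group there is no replicate check on any difference, and no p-value was computed. The technical error of a difference combines the software's error of both spots, averaged over replicate spots and not reduced for their number. Its median was 0.20 on the log2 scale, and many bright genes shared the value 0.204. A difference was set against 2 times this technical error. The technical error holds no spread between animals. Over 203 replicated probes well above background, the SD of the difference between replicate spots was smaller, with a median of 0.07. Spot noise was also taken from probes printed 10 times, 263 in all. Pairs of replicate spots were compared for the 203 of them with every spot well above background on both arrays. This leaves out dim probes with spots near background. The software's population outlier flag falls on the 263 probes alone, on 135 of their 2630 spots and on 0 of the 40749 others. Flagged spots were therefore kept for the noise estimate. This choice was made after a first estimate without them had found 0 pairs of replicate spots 2-fold apart.

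Gene lists, 27 of programmes and 14 of cell types, the rule for named genes and the alternative settings, other than those named below as added, were fixed before the data were examined. A list's median log2 difference was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its median lay outside the central 95% of random medians. This describes these 2 libraries only. List members counted as higher or lower at a 1.5-fold difference that also exceeded 2 times the technical error. Of 1009 listed genes, 820 were measured. The text names the 10 genes with the largest difference in each direction whose measured probes all had the same direction, the 3 largest bounds in each direction, up to 4 members per list with the largest difference, and Pparg and Pkhd1. Members of the mitosis, adipocyte and adrenal lists seen on 1 array alone, and further adipocyte genes, were named outside this rule after the values were seen. Some genes that this rule selects are not reported here. A gene not well above background on 1 array has only a bound there. The bound sets the bright array's value against the higher of the probe's own value and the lowest value well above background on the dim array.

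The procedure was tested on simulated data for a comparison of 1 array with 1 array over 10485 genes, with noise taken from the replicate spots. All 66 genes changed 4-fold passed a 2-fold threshold, as did 65 of 67 changed 2.5-fold and 3 of 67 changed 1.5-fold. Of 9785 unchanged genes, 12 passed. All 20 lists of 25 genes with a shift of 0.2 were recovered, and 0 of 20 unshifted lists stood apart. The simulated noise was independent between genes and the lists were drawn at random. The simulation therefore does not show how often lists whose members vary together would stand apart. Smaller shifts of lists were not simulated.

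Alternatives were quantile, cyclic loess and median scaling, the 75th percentile of detected probes, the unscaled value table, other filters on dim probes, a mean over probes, flagged spots kept, and unmatched or unshared lists. Added after seeing the data were normexp background correction with an offset of 50 on median signals and the removal of the sixth and the seventh of 10 equal bands of grid rows. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1. Figures were drawn with matplotlib 3.10.9.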

Results

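The data compare 1 array of pooled kidney RNA from pioglitazone-treated female PCK rats with 1 array from vehicle-treated females. They address how a PPAR-gamma agonist alters gene expression in a cystic kidney. Across 10484 measured genes the arrays correlated with r = 0.997 (Spearman's rho 0.997), a correlation across genes, which are not independent replicates. Of these genes, 97.3% differed by less than 1.5-fold. The number of arrays limits the precision, and all differences below are pioglitazone relative to vehicle on the log2 scale unless a fold is given.

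The pioglitazone pool had lower expression of cell division, matrix, complement and immune genes and higher expression of proximal tubule, intercalated cell and mitochondrial metabolism genes. The shifts were small and spread over many genes. Of 41 gene lists, 18 stood apart as lower and 7 as higher, where random lists of independent genes would give 2.05. Members of a list can vary together and some lists share members. How many lists would stand apart between 2 pools of the same treatment is therefore not known. The list of mitotic genes had a median of -0.35, that of macrophage markers -0.33 and that of matrix genes -0.26. The proximal tubule list had a median of 0.17 and the intercalated cell list 0.21.

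Genes of mitosis were lower as a group. Of 29 measured members of the G2/M list, 26 had negative differences, and 4 were lower by the 1.5-fold criterion while 0 were higher. These were Ect2, a regulator of cytokinesis (-0.81), the cyclins Ccnb2 (-0.68) and Ccna2 (-0.67), and the spindle checkpoint kinase Ttk (-0.63). Of 4 further members detected on 1 array alone, the centromere histone Cenpa (at least 9.70-fold) and Aurkb (at least 1.29-fold) were seen with pioglitazone, and Cenpf (at least 1.61-fold) and Prc1 (at least 1.51-fold) with vehicle. In the DNA replication list 4 of 32 members were lower, with a median of -0.09. Mcm10, a replication initiation factor, was at -0.97, Gins2 at -0.76, the ribonucleotide reductase subunit Rrm2 at -0.63 and cyclin E1 (Ccne1) at -0.59. The G1 regulator list had a median of -0.15 over 18 genes, none of which met the 1.5-fold criterion. It mixes cyclins with cell cycle inhibitors, so its median does not show less or more cell cycle entry. The inhibitor Cdkn2b was at -0.48 and the cyclin Ccnd2 at -0.48.

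Matrix genes had negative differences in 32 of 34 measured members, and 4 met the criterion. S100a4, a calcium-binding protein of fibroblasts and macrophages, was at -1.12, the microfibril gene Fbn1 at -0.65, the collagen Col3a1 at -0.63 and the membrane protease Mmp14 at -0.62. The TGF-beta and BMP list had a median of -0.11 over 21 genes, with 2 lower, Tgfb2 (-0.71) and Inhba (-0.60). The Wnt list had a median of -0.16 over 17 genes, with 2 lower, Wnt11 (-0.85) and Wnt4 (-0.73). Fibroblast and pericyte markers had a median of -0.08 over 16 genes, with Col1a2 at -0.42 and no member past the criterion.

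Immune genes were lower across several lists. Macrophage markers were negative in 23 of 24 genes, with 3 lower: the integrin Itgam (-0.77), the lipid receptor Trem2 (-0.66) and Gpnmb (-0.62). The lymphocyte list had a median of -0.25 over 22 genes, with Cd2 at -0.88 and Cd3g at -0.55, while Ccr7 was at 0.63, within 2 times its error. Complement genes had a median of -0.34 over 15 genes, with 2 lower, factor D (Cfd, -1.18) and factor B (Cfb, -0.96), and C3 at -0.55. The interferon response list had a median of -0.22 over 22 genes, led by the transcription factor Irf7 (-0.82). Cytokines and NF-kB targets had a median of -0.15 over 23 genes, led by the interleukin-1 receptor antagonist Il1rn (-0.63).

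Markers of tubular injury were negative in 23 of 26 genes, with a median of -0.31. Havcr1, which encodes kidney injury molecule 1, was at -0.60, S100a6 at -0.56 and Lcn2, which encodes neutrophil gelatinase-associated lipocalin, at -0.49. Immediate early genes had a median of -0.16 over 21 genes, with Egr2 at -0.44 and Fos at -0.43. Urothelial markers had a median of -0.33 over 9 genes, with the keratin Krt15 (-1.03), Tp63 (-0.62) and Psca (-0.60) lower. Erythroid genes had a median of -0.30 over 8 genes, with the haemoglobin chaperone Ahsp at -0.97 and Hbb at -0.47. The distal convoluted and connecting tubule list had a median of -0.13 over 10 genes, although its member Klk1 was at 0.45. The ribosomal protein list stood apart as lower with a median of 0.01, because its matched random lists lay between 0.02 and 0.10, and its sign turned between scalings.

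Proximal tubule transporters had positive differences in 29 of 32 genes, none of which met the 1.5-fold criterion. Slc7a7, an amino acid transporter, was at 0.33, the glucose transporter Slc5a1 at 0.33 and the sulfate transporter Slc26a1 at 0.31. Intercalated cell markers were positive in 15 of 17 genes, with Hepacam2 at 0.43 and the transcription factor Foxi1 at 0.42. Fatty acid oxidation and PPAR-alpha targets were positive in 32 of 37 genes, with a median of 0.13, Acot4 at 0.57 and Acaa2 at 0.38. Oxidative phosphorylation genes were positive in 32 of 34, with a median of 0.13 and Cox7b at 0.31. These counts of positive genes are set against 0, while the median over all measured genes was 0.03, and 0.04 above the median signal. They therefore look stronger than the ranking among random lists. All 14 measured genes with Trappc symbols were also positive, at only the 76.4 percentile of random lists. Gluconeogenesis and amino acid metabolism had a median of 0.20 over 22 genes, with Fah at 0.33 and Pck1 at 0.31. The xenobiotic metabolism list had a median of 0.20 over 25 genes, with Cyp1a1 at 0.68, and dropped to 0.02, inside its random range, when dim probes were included. The renin-angiotensin list had a median of 0.16 over 9 genes. The differences of Slc7a7, Slc5a1, Slc26a1, Acaa2, Cox7b, Fah and Pck1 were within 2 times their error.

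**Figure D1:**
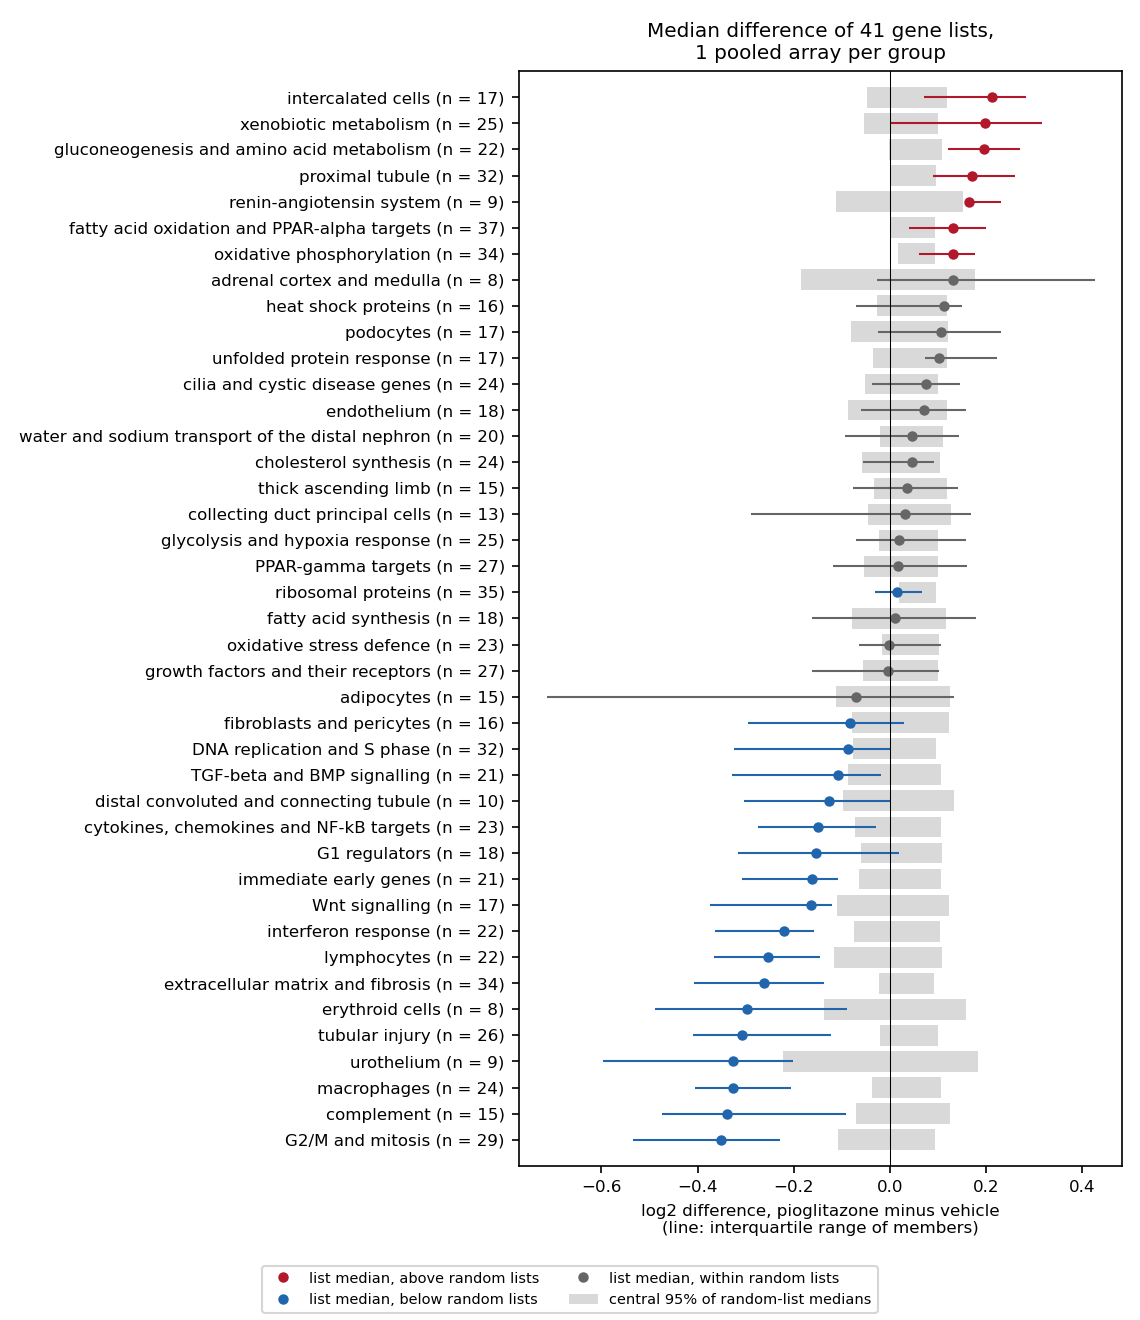
Median log2 difference, pioglitazone minus vehicle, of 41 gene lists (points) with the interquartile range of members (lines) and the central 95% of medians of matched random lists (grey bars), from 1 pooled array per group. Lists of mitosis, complement, macrophages and urothelium lie lowest, and intercalated cell and metabolic lists lie highest.

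PPAR-gamma targets as a list did not stand apart, with a median of 0.02 over 27 genes at the 37.0 percentile of random lists. Ucp1 was at -1.78, Abcg1 at -0.47 and Gpd1 at 0.45. Pparg itself was at -0.30, a mean over 10 spots. Its technical error of 0.23 is an average per spot that was not reduced for their number. No probe was assigned to Pkhd1, which is not analysed here. Fatty acid synthesis genes went both ways around a median of 0.01, with Acacb (0.75) and Acss2 (0.63) higher and Scd (-1.98) and Thrsp (-0.94) lower. Adipocyte markers had a median of -0.07 over 15 genes with 4 lower, Retn (-2.27), Ucp1, Cfd and Thrsp. Car3 on the same list was detected with vehicle alone, at least 5.15-fold lower with pioglitazone.

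The fibroblast, renin-angiotensin, ribosomal, DNA replication, G1, TGF-beta, Wnt, distal convoluted tubule and xenobiotic lists no longer stood apart under at least 1 alternative setting.

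The remaining lists lay within their random ranges, although podocytes, fatty acid synthesis and the unfolded protein response stood apart as higher, and principal cells as lower, under at least 1 alternative setting. Medians were 0.05 for cholesterol synthesis, 0.02 for glycolysis and hypoxia, 0.05 for distal sodium and water transport and 0.07 for cilia and cystic disease genes. They were -0.003 for growth factors and their receptors, 0.10 for the unfolded protein response, 0.11 for heat shock proteins and -0.003 for oxidative stress defence. Among cell types, the thick ascending limb list had a median of 0.03, principal cells 0.03, podocytes 0.11, endothelium 0.07 and the adrenal list 0.13. The water channel Aqp2 was at -0.34, within 2 times its error. Akr1b7 on the adrenal list was at 1.12, while Cyp11b1 on that list was detected with vehicle alone, at least 4.27-fold lower with pioglitazone.

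**Figure D2:**
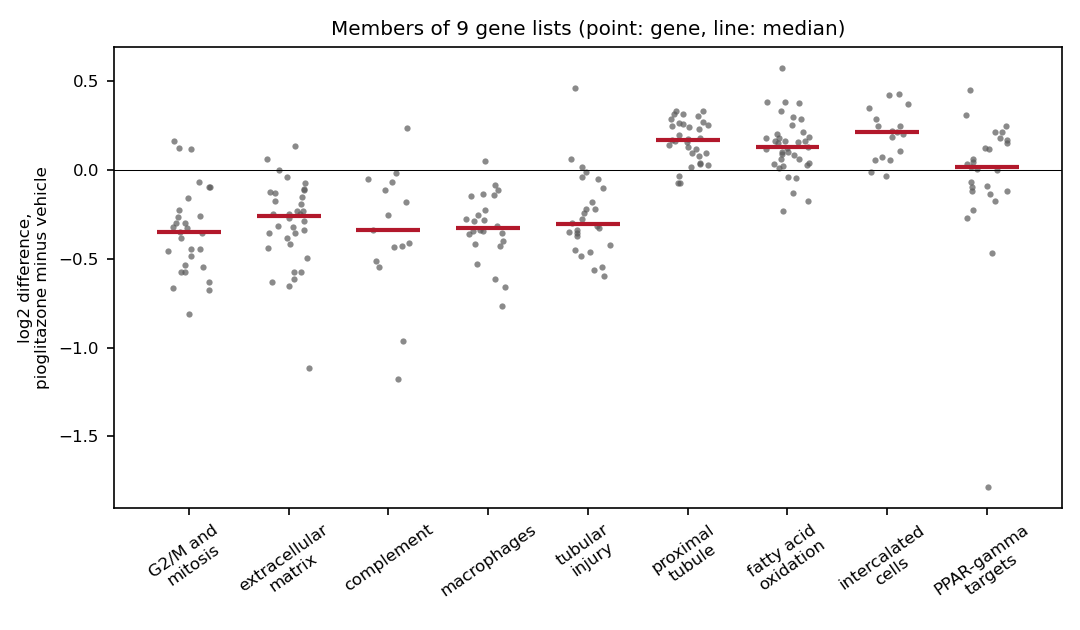
Log2 difference, pioglitazone minus vehicle, of each measured gene (points) in 9 lists, with the list median (lines). Most members of the mitosis, matrix, complement, macrophage and injury lists lie below 0, and most proximal tubule members lie above it.

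Few single genes differed strongly, and most of these had dim signals. At 2-fold or more, 17 genes were higher and 31 lower, a higher share of 35.4%. Over the alternatives that share ran from 12.5% with normexp correction to 51.1% in the unscaled table. It was 46.8% with median scaling and 29.4% without the sixth and the seventh of 10 equal bands of grid rows. The largest positive differences reported here were Naa40 (2.05), Zp4 (1.94), Rnf112 (1.78), Zbtb1 (1.77), Gucy2e (1.62), Psg29 (1.35), Klk1c9 (1.25), Cyp2d3 (1.23) and Or10d5j (2.29-fold). The largest negative ones were Or2ak4 (-3.24), Gpha2 (-3.05), Retn (-2.27), Cep76 (-2.07), Fgfbp1 (-2.00), Scd (-1.98), Ucp1 (-1.78), Chrm1 (-1.71), Lypd2 (-1.65) and Celf3 (-1.48). Lypd2 was bright, with signals of 2150 and 725, and Ucp1 was lower in all 10 of its spots, including flagged ones left out of its value. Detected on 1 array alone were Cenpa, Or4p18 (at least 8.59-fold) and Grik4 (at least 7.89-fold) with pioglitazone, and Crx (at least 11.0-fold), Or5b102 (at least 8.65-fold) and Acsl6 (at least 7.76-fold) with vehicle. In all, 257 genes were detected with pioglitazone alone and 113 with vehicle alone, of which 25 and 33 had bounds of 2-fold or more. The pioglitazone array had the lower limit of detection, with a lowest signal well above background of 7.16 against 7.66. The counts of 257 and 113 therefore do not show that more genes were switched on.

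Spot noise may account for such differences at low signal, depending on how it is estimated. Pairs of replicate spots on the same array differed 2-fold in 1.47% of cases below a signal of 50, from 5 stray spots among 680, which would give 29.1 of the 1978 genes in that class, where 28 were seen. Without flagged spots 0 of 16904 pairs differed 2-fold in any class and 0 genes were expected, and the choice to keep those spots was made after seeing this. In the next 3 classes of rising signal 14, 2 and 4 genes differed 2-fold and 0 were expected in each. That expectation rests on 0 stray spots among 800, 1120 and 980 replicate spots. So few spots cannot exclude a low rate of stray spots, so these genes are not shown to exceed spot noise. In the brightest class 5.47 were expected from 1 stray spot and 0 were seen. At 1.5-fold, 164 genes differed below a signal of 50, where 87.9 were expected from spot noise, or 44.6 without flagged spots. These expected counts do not apply the further limit of 2 times the technical error. Among list members counted at 1.5-fold, Mcm10, Rrm2, Tgfb2, Inhba, Wnt11, Itgam, Cd2, Tp63 and Psca had signals below 50 on both arrays. Of measured genes, 19.9% lie in the sixth and the seventh of 10 equal bands of grid rows, which held 9 of the 17 genes higher and 7 of the 31 lower by 2-fold. Of the genes named above, S100a4, Cfd, Trem2, Cd2, Inhba, Krt15, Akr1b7, Cyp11b1, Aurkb, Klk1, Egr2, Foxi1, Col1a2, Slc26a1, Naa40, Zp4, Rnf112, Zbtb1, Gucy2e, Cyp2d3, Cep76, Or4p18, Grik4, Or5b102 and Acsl6 lie there. With normexp background correction 1 gene was higher and 7 were lower by 2-fold.

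**Figure D3:**
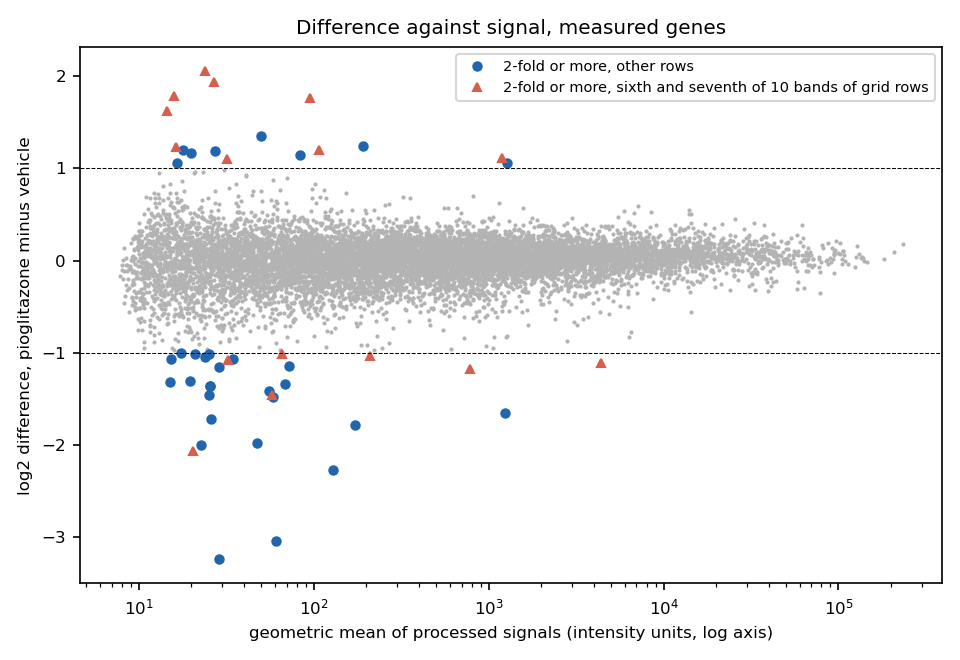
Log2 difference, pioglitazone minus vehicle, against the geometric mean signal of both arrays (log axis) for 10484 measured genes (grey), with genes at 2-fold or more marked by grid position. Large differences crowd at low signal, and 16 of the 48 marked genes lie in the sixth and the seventh of 10 equal bands of grid rows.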

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

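The tests in this part were chosen after the result was seen. A pair of probes without a gene symbol, outside every comparison above, gave signals well above the vehicle array: A_44_P105396 was 8.31-fold higher with pioglitazone and A_44_P285155 7.45-fold higher. Another, A_43_P16196, was 7.96-fold lower, with signals of 67.1 and 8.93. Each was read from 1 spot. Among 15335 measured unnamed probes, 44 were higher and 55 lower by 2-fold or more.

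All 3 probes lie in the sixth and the seventh of 10 equal bands of grid rows, where large differences crowd. Those rows held 20.6% of measured spots and 44.0% of the spots that differed 2-fold, 77 in all, of which 35 were higher and 42 lower. The tables argue against a surplus of dim spots as the source, since the share of dim spots there was only 1.04 times that elsewhere while 2-fold differences among dim spots were 2.87 times as frequent. Local spot defects may be the source and stay open: replicate spots strayed from their own probe 0.84 times as often there (95% exact interval 0.15 to 3.01), from 3 of 428 spots against 14 of 1679, too few to decide. A first version of that test had left out spots with outlier flags, which removes stray replicates, and gave 0 of 412 against 6 of 1597. No biological explanation was tested for a grid position.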

How the results depend on the processing

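Normexp correction and the removal of the middle grid rows were chosen after seeing the data. No list standing apart changed direction and remained apart under any alternative. Of the 25 lists, 25 kept their side with median scaling, the 75th percentile of detected probes, the unscaled table and flagged spots kept, 24 with a mean over probes, 23 with cyclic loess, without the middle rows, with no filter on dim probes, with unmatched random lists and without shared members, and 22 with quantile scaling and normexp. Above the median signal 20 of 24 did. The fibroblast, renin-angiotensin, ribosomal, DNA replication, G1, TGF-beta, Wnt, distal convoluted tubule and xenobiotic lists each lost their place under at least 1 alternative. Others gained one: podocytes as higher with quantile scaling (98.0 percentile), a mean over probes (97.9) and without shared members (98.2), fatty acid synthesis as higher above the median signal (98.1), the unfolded protein response as higher without the middle rows (98.4) and principal cells as lower with normexp (0.21). Over 5 scalings 24 of the 25 medians kept their sign, although some came close to 0. The fibroblast median lay between -0.096 and -0.0006, that of DNA replication between -0.10 and -0.005 and that of TGF-beta between -0.12 and -0.02. The unscaled table moved the median of all genes to 0.11. Counts of single genes were less stable. Against 17 higher and 31 lower at 2-fold, there were 201 and 210 with no filter on dim probes, 2 and 3 above the median signal, 1 and 7 with normexp, and 88 and 196 at 1.5-fold. Without the middle rows 10 were higher. Bounds of 2-fold or more, 25 with pioglitazone alone and 33 with vehicle alone, numbered 2 and 2 with normexp, and 15 and 14 without the middle rows. The normexp setting changed the input signals, the background method and the offset together, and the cause was not tested for any setting. Bounds were not defined without a filter, above the median signal or for a mean over probes. The planned normexp on mean signals was not run, because mean signals were not among the values used here. No paired analysis was possible because each group has 1 array.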

Other observations

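The tests on dilution of other cell types, on fat tissue and on defective spots of Ucp1 in this part were chosen after the result was seen. Genes above the median signal, chosen after their values were seen, add to the picture. Kap, which encodes a kidney androgen-regulated protein, was at 1.05 and the proton pump gene Atp12a at 0.70. All 10 measured kallikrein genes (Klk) were positive with a median of 0.52, between 0.47 and 0.60 over 5 scalings, although close paralogs can share probe signal. Lower were the mesothelial gene Msln (-0.84), Upk3bl1 (-0.87) and the acute phase gene Serpina3n (-0.83). Of 118 symbol families with at least 10 members, 12 stood apart as higher and 10 as lower, where random lists of independent genes would give 5.9. Olfactory receptors were among the higher ones: the Or family had a median of 0.15 over 216 genes, 159 of them positive (random range -0.05 to 0.03, and 0.14 to 0.23 over 5 scalings), and the Olr family 0.17 over 13. That is about the size of the proximal tubule median of 0.17.

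A hypothesis for the lower proliferation, matrix and immune lists and the higher proximal tubule and intercalated cell lists is a response to treatment. The ranking already matched lists on mean expression, so the loess test says little about a bias that depends on signal. After cyclic loess 92.0% of the lists standing apart still did so. Without the middle rows 92.0% were kept, so defects in those rows alone did not carry the pattern. Dilution of every other cell type by more tubule tissue would lower all such markers alike. Endothelial and podocyte markers instead lay 0.40 above macrophage markers (95% bootstrap range over genes 0.29 to 0.48). That range treats genes as independent and holds no spread between pools. The values bear only on a like dilution of these cell types, and an uneven change in the make-up of the pools was not tested. A difference between the pools or between their arrays, unrelated to treatment, may equally account for the pattern. With 1 array per group neither can be told apart from the drug. The Or family moved by 0.15, about as much as the proximal tubule list, and the source of that shift was not tested.

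Retn, Ucp1, Cfd and Thrsp, known from fat cells, had differences from -0.94 to -2.27. Defective spots are not a candidate source for Ucp1, which was lower in 10 of 10 spots, flagged spots included. Its value above rests on the 6 spots without a flag. Less fat tissue in the pioglitazone pool, with each fat gene otherwise unchanged, stays open. The whole adipocyte list, 17 genes with the 2 seen on 1 array at their bounds, had a median of -0.071 (95% bootstrap range -0.94 to 0.15). That list includes the 4 genes that prompted the test, and the lower end of the range is the value of Thrsp. The range therefore cannot decide the question. Beside these 4 genes, Car3 was at least 5.15-fold lower, with signals of 38 and 7.82, and Acvr1c was at -0.49, past 2 times its error of 0.23. Not all members were lower beyond 2 times their error: Adipoq was at -0.10, Fabp4 at -0.07, Cidec at 0.00 and Lpl at 0.15. A loss of fat alone would lower these genes too, unless kidney cells also express them. Expression of list members in kidney cells was not tested.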
